A study of Mus musculus with 6 samples.

How the data were processed

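Gene expression was measured in mouse embryonic stem cells on Illumina bead arrays, with 1 array per sample. Per the labels, the cells were grown with serum and leukemia inhibitory factor on feeder fibroblasts from mouse embryos whose division had been blocked with mitomycin C. They received a plasmid for a short hairpin RNA by electroporation, and puromycin was applied from 24 h after transfection for 48 h before RNA was taken. The labels give 3 arrays of cells with a hairpin against Chd8, called shChd8 here, and 3 arrays of control cells. What the control vector carried is not given in the sources used here. Replicate numbers follow the order of the samples and pair nothing. The 6 arrays lay on 1 slide, and the array positions of the groups did not mix, so position and group cannot be told apart. The labels do not say that the arrays came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

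The deposited table of non-normalized values holds the intensity of each probe on a linear scale and a detection p-value per probe and array, per the file headers. GenomeStudio is named in the submitters' processing notes, and its version is not given in the sources used here. The values in that table were all above 0 and differed in median between arrays, so they had been neither background subtracted nor normalized between arrays. A deposited table of normalized values also holds intensity on a linear scale. Each of its columns had the rank order of the array's non-normalized intensity (lowest Spearman rho 1), and its sorted values differed from the mean of the sorted non-normalized values by a median of 0.0038%. This is what quantile normalization without background subtraction gives. The medians of these normalized columns lay between 112.1 and 112.2.

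The main analysis started from the non-normalized intensity and used limma 3.58.1 in R 4.3.3. Background was corrected and arrays were quantile normalized with neqc, which took the negative control distribution from the detection p-values and added an offset of 16, and values were then on the log2 scale. A probe was tested when its detection p-value was under 0.01 on at least 3 of the 6 arrays. Each probe was fitted with lmFit and eBayes without a covariate, two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tested probes. A probe was called at an adjusted p under 0.05. A gene was called when at least 1 of its probes was called, in the direction of its probe with the lowest p, and its values are those of that probe. A probe that was detected on no array of a group has only an upper bound there. For such a gene the fold is given as "at least", from the mean of the bright group against the mean over the dim group's arrays of the higher of the probe's own value and the lowest value of a detected probe.

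Of the 45281 probes, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 had none. The symbols of 34807 probes were updated through gene identifiers of RefSeq (assembly GRCm38.p6), and the rest kept the annotation's symbol. The annotation names no genome build for the probes, and no coordinates are given. No gene was named from a probe with several symbols. Probes of gene families with near-identical members, such as Zscan4, Pramel and histone genes, can bind the RNA of more than 1 member, and their values are uncertain in that respect.

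The lists of genes were written from textbook knowledge before the data were examined, as were the design, the rule for named genes and all but 2 of the alternative settings. They covered chromatin remodelling ATPases including the CHD family, pluripotency factors, Wnt/beta-catenin targets, p53 targets, E2F and replication genes, mitosis genes, linker histones, primitive streak and mesoderm, endoderm, neural and epiblast, and trophectoderm genes. They also covered feeder fibroblast markers, interferon-response genes, 2-cell-stage genes, unfolded protein and integrated stress response genes, hypoxia and glycolysis genes, cholesterol synthesis genes, Nodal and BMP targets, Hox genes, imprinted genes, autism-associated genes, cytosolic ribosomal proteins and the mitochondrial respiratory chain. Some listed names had no probe among those used here. A list was tested with limma's camera at its preset correlation of 0.01, on the probe with the highest mean of each gene, when at least 5 members were measured. Medians, named members and counts adjusted over a list alone rest on that brightest probe. Members called over all genes tested are counted by any probe, and the count on the brightest probe is given where it differs. Adjustment was over the 22 tested lists of 23. Camera with an estimated correlation and fry were run beside it. Fry tests whether the members of a list move on balance in 1 direction, without comparing them with other genes.

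The genes named in the report are Chd8, then the 10 called genes with the largest rise and the 10 with the largest fall whose groups did not overlap, leaving out names that are only a clone, locus or predicted gene, and then up to 4 members of each list with the lowest p. Chd8 also received an exact two-sided permutation test over the 20 assignments of the 6 arrays, whose smallest possible p is 0.1.

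The procedure was tested on simulated data made for the comparison of shChd8 with control, with 17904 probes tested and 200 of their genes changed by known amounts. Of 50 genes changed per size, 4% were called at a 1.5-fold change, 34% at 2-fold, 68% at 3-fold and 92% at 4-fold. Of the calls, 5.85% were of unchanged genes and 0 had the wrong sign. The shifted list was called, as was 1 list that had not been shifted. Noise was drawn for each probe on its own, so the simulation could not show how correlation between genes affects the calls of genes or lists.

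Alternatives covered the background correction, the scaling between arrays including the deposited normalized values, the filter on dim probes, the test, the threshold, the set test, the choice of probe and the removal of each array in turn. A fit with the median of the feeder markers per array as a covariate was added after the data had been seen, and the lists were tested in it at the preset and at an estimated correlation. The number of arrays, 3 per group, limits the precision of every value.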

Results

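The series asked which genes depend on chromatin remodellers in mouse embryonic stem cells, and the part described here concerns Chd8, an ATP-dependent remodeller of the CHD family. Transcripts were measured on 3 arrays of cells with a hairpin against Chd8 and 3 arrays of control cells. Mean intensity was 408.6, 389.9 and 413.1 on the control arrays and 419.5, 463.5 and 497.5 on the shChd8 arrays, before normalization. Between 16482 and 17440 of the 45281 probes were detected per array. After normalization, the correlation across probes lay between 0.975 and 0.984 among control arrays, between 0.982 and 0.987 among shChd8 arrays, and between 0.954 and 0.977 across the groups. Genes are not independent replicates, and these correlations only describe the arrays.

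Chd8 itself was lower in all 3 shChd8 arrays than in all 3 control arrays. Its main probe (ILMN_2703082) had a normalized log2 intensity of 9.96 ± 0.06 (SD, n = 3) in control and 8.57 ± 0.19 (SD, n = 3) in shChd8 cells. The log2 change was -1.39 with a standard error of 0.15, which left 38.1% of the control level (limma adjusted p = 0.00907). This size depended on the processing. The change was -1.21 both without background correction and with the deposited normalized values, and -1.16 with median scaling, against 0.18 for all probes. The exact two-sided permutation test gave p = 0.1, the smallest that 3 arrays against 3 can give. The other Chd8 probe (ILMN_2558471) was detected on no array, and its log2 values of 4.72 and 4.76 lie at background and carry no information on the knockdown. The log2 change was below 0 in all 17 alternatives. Groups that do not overlap favour this, and a change of the filter, or an unmoderated or trended test, leaves the log2 change as it was. The call on the main probe was lost with an unmoderated test of each probe (adjusted p = 0.061) and with the feeder marker median as a covariate (adjusted p = 0.329), where the log2 change was -1.56 and the standard error 0.26. The residual SD was 0.19 in both fits, and the standard error grew because the covariate overlaps with the groups.

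**Figure D1:**
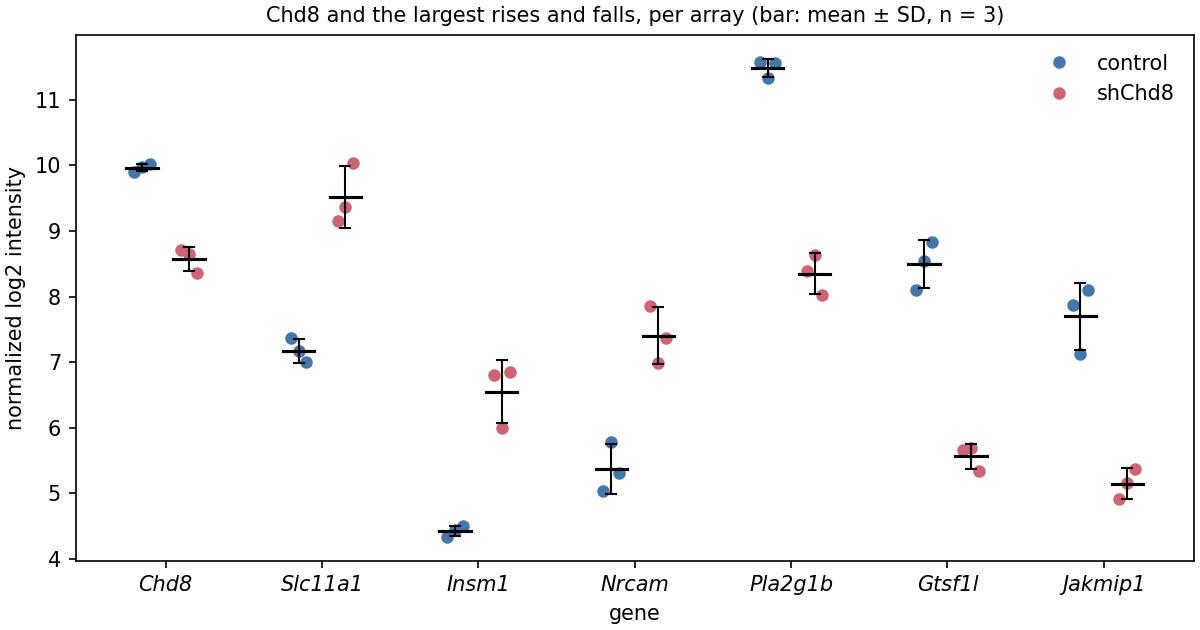
Normalized log2 intensity per array for Chd8 and for the 3 genes with the largest rise and the 3 with the largest fall. Points are arrays, horizontal lines are group means and bars are SD (n = 3). Chd8 has a mean of 9.96 in control and 8.57 in shChd8 arrays, and the groups do not overlap for any gene shown. Insm1 was below detection on the control arrays, so its place among the 3 rests on a value at background.

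The comparison of shChd8 with control cells asked which transcripts differ when Chd8 is reduced by a hairpin. The labels name no second hairpin and no rescue. Effects of the hairpin on other transcripts therefore cannot be told apart from effects of less Chd8. Of 9711 genes tested, 206 rose and 296 fell, so that 59.0% of the 502 called genes fell. Among the falls Pla2g1b, a secreted phospholipase of the pancreas, had the lowest log2 change at -3.14 (SE 0.19), followed by Gtsf1l, a relative of a germ cell factor, at -2.93 (SE 0.21). Among the rises, Slc11a1, a divalent metal transporter known from macrophage phagosomes, had the highest log2 change at 2.34 (SE 0.24). Every called gene differed by at least 1.5-fold, and the smallest absolute log2 change among them was 0.62.

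Insm1, a zinc-finger factor of neuroendocrine cells, was detected on no control array and on 3 of 3 shChd8 arrays, where it was at least 2.73-fold higher. Nrcam, a neuronal cell adhesion molecule, rose by 2.03 (SE 0.26). The DNA end-joining factor Nhej1 rose by 1.65 (SE 0.22) and the retinoblastoma gene Rb1 by 1.64 (SE 0.18). Cryab, a small heat-shock protein, rose by 1.76 (SE 0.35), and Capn2, a calpain protease, by 1.57 (SE 0.32). The other large rises were those of the platelet chemokine gene Ppbp at 2.00 (SE 0.27), Adap1 at 1.73 (SE 0.21) and Ms4a10 at 1.73 (SE 0.35). Adjusted p values of these rises lay between 0.00886 and 0.0395.

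The genes with the largest falls included Cela2a, a pancreatic elastase, with a log2 change of -2.31 (SE 0.19), and Jakmip1 with -2.55 (SE 0.26). Tekt1, a tektin of cilia and sperm flagella, changed by -2.01 (SE 0.17) and Aurkc, the Aurora kinase of meiosis, by -1.99 (SE 0.33). The imprinted placental gene Phlda2 had a log2 change of -1.90 (SE 0.15), the signalling adaptor Gab1 -1.88 (SE 0.15), the myosin light chain Myl4 -1.94 (SE 0.19) and Bcas1 -1.94 (SE 0.23). Adjusted p values of these falls lay between 0.00329 and 0.028. All 20 genes kept their direction in each of the 332 fits of these genes under other settings, and the call held in 257 of them. The genes had been chosen for groups that did not overlap, which favours a kept direction. A change of the filter, or an unmoderated or trended test, leaves the log2 change as it was. The kept direction is therefore no test of these genes.

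**Figure D2:**
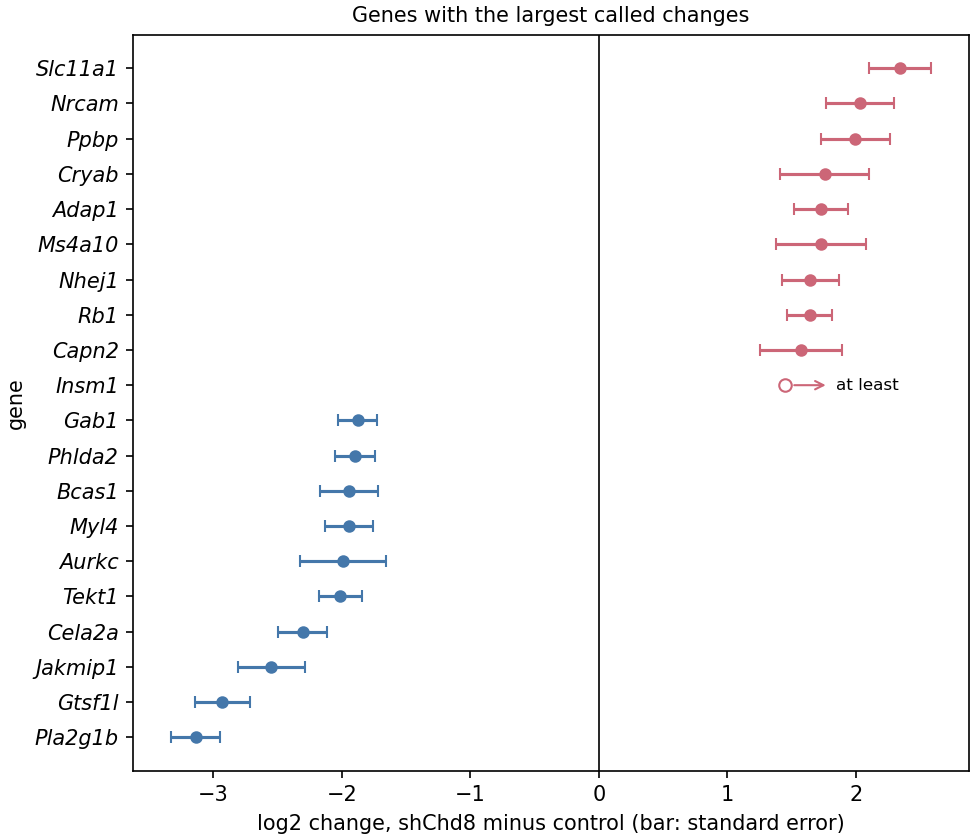
Log2 change, shChd8 minus control, of the 10 called genes with the largest rise and the 10 with the largest fall. Filled points are the fitted changes and bars are standard errors from limma with 3 arrays per group. The open point is the lower bound of 1.45 for Insm1, which was detected on no control array, so its place among the 10 rests on a value at background. The other values run from -3.14 for Pla2g1b to 2.34 for Slc11a1.

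The groups did not overlap for any of the 502 called genes, which the call itself favours, and they did not overlap for 37.7% of all tested genes. Chance gives 10% for a single probe. It gives more here, since the probe with the lowest p stood for each gene (14568 probes for 9711 genes). Of the 200 called genes with more than 1 tested probe, 37 had another probe called the same way, 21 had a probe of opposite sign and 0 had a probe called the opposite way. The split of calls depended on the scaling: median scaling moved the median log2 change of all probes from -0.01 to 0.18 and gave 1165 genes higher and 176 lower. The number of calls depended on which array was left out, with 44 genes called without control replicate 1, 679 without control replicate 2, 34 without control replicate 3, 15 without shChd8 replicate 1, 27 without shChd8 replicate 2 and 435 without shChd8 replicate 3. So did the split, with 360 higher and 319 lower without control replicate 2 and 226 and 209 without shChd8 replicate 3. The other removals gave more falls than rises, up to 1 higher and 14 lower without shChd8 replicate 1.

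Genes induced by the tumour suppressor p53 were higher as a group. Of 26 measured members 9 rose and 0 fell over all genes tested. On the brightest probe of each gene 8 rose, and 15 rose adjusted over the list alone. The ninth was Mdm2, which encodes the ubiquitin ligase of p53, at 0.91 (SE 0.18) on another probe. The median log2 change was 0.79 (camera adjusted p = 1.49e-07, and adjusted p = 0.259 with an estimated correlation; fry adjusted p = 0.00953). Plk2, a polo-like kinase, rose by 1.37 (SE 0.17), the apoptosis gene Bbc3, which encodes Puma, by 1.02 (SE 0.17), the stress-response gene Ddit4 by 1.04 (SE 0.18) and Trp53inp1 by 0.92 (SE 0.15). Each shChd8 array lay above each control array in the median deviation of the members, with 0.42, 0.27 and 0.28 against -0.20, -0.26 and -0.48. The feeder markers were also higher in the shChd8 arrays.

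Markers of embryonic fibroblasts, the feeder cells of these cultures, were higher in the shChd8 arrays. Of 27 measured markers, 26 had a log2 change above 0, and the median was 0.91. Fbln2, a matrix protein, rose by 1.13 (SE 0.22) and Tagln, an actin-binding protein of smooth muscle and fibroblasts, by 1.06 (SE 0.22). Twist1 had a log2 change of 1.00 (adjusted p = 0.0514) and Acta2 of 1.16 (adjusted p = 0.06). Fbln2 and Tagln were the 2 called over all genes tested, and 14 rose adjusted over the list alone (camera adjusted p = 4.77e-08, adjusted p = 0.499 with an estimated correlation, and fry adjusted p = 0.166). The marker median per array was -0.16, -0.37 and -0.85 in control and 0.95, 0.45 and 0.03 in shChd8, so the arrays of a group differed widely. With this median as a covariate, a fit added after the data had been seen, limma called 0 genes, with 1450 probes at an unadjusted p under 0.05 against 4292 without it. All 502 genes kept their sign there, with median changes of 0.74 against 0.96 for the rises and -0.84 against -0.95 for the falls, while the median standard error went from 0.17 to 0.28. The p53 list kept its camera call in that fit at the preset correlation (median 0.26, adjusted p = 0.000303) and not with an estimated one (adjusted p = 0.366), while the Hox median was -0.24 (adjusted p = 0.465) and the adjusted p was 0.146 for cholesterol synthesis and 0.543 for both the mitosis and the mesoderm list.

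Hox genes, which set position along the body axis, and primitive streak and mesoderm genes shifted upward as lists without a called member. The 15 measured Hox genes had a median log2 change of 0.50, and 14 of them were above 0 (camera adjusted p = 0.00303, adjusted p = 0.643 with an estimated correlation, and fry adjusted p = 0.309). Hoxd10 had a log2 change of 1.11 (adjusted p = 0.0791) and Hoxa5 of 1.06 (adjusted p = 0.161), and Hoxd8 and Hoxd9 had 0.66 and 0.61. The Hox medians per array overlapped, with control replicate 2 at 0.20 and shChd8 replicate 3 at -0.26. The Hox median change was 0.85 without shChd8 replicate 3, 0.75 with median scaling, against 0.18 for all probes, 0.30 with normexp without controls, 0.23 without background correction, 0.28 without a filter and 0.24 with the deposited normalized values. Of the 11 mesoderm genes 9 were above 0, with a median of 0.53 (camera adjusted p = 0.0406, adjusted p = 0.499 with an estimated correlation, and fry adjusted p = 0.166). Tbx6 was detected on no control array and was at least 1.19-fold higher, and with Tbx6 at this bound the mesoderm median was 0.47. Foxc2 had a log2 change of 0.88, Gata2 of 0.73 and Gsc of -0.50. The number called by limma was 0 for both lists, also adjusted over the list alone, while at an unadjusted p under 0.05 there were 2 Hox genes, both higher, and 6 mesoderm genes higher and 1 lower. The feeder markers moved in the same direction as both lists. The mesoderm call was lost in 13 of 20 alternatives. Among these were the fits without control replicate 3 (adjusted p = 0.132), without shChd8 replicate 1 (0.0591) and without shChd8 replicate 2 (0.136). Others were normexp without controls (0.0703, median 0.28), no background correction (0.0748, median 0.19), median scaling (0.0708), the deposited normalized values (0.0748, median 0.19) and the looser (0.0751) and stricter (0.218) filter. Without a filter the call held at a median of 0.15.

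Genes of cholesterol synthesis were lower as a group. Dhcr7, which catalyses the last step to cholesterol, fell by 1.27 on the log2 scale (SE 0.19). Srebf2, which encodes a regulator of the pathway, fell by 0.89 (SE 0.19) on 1 probe and had -0.36 on its brightest one (adjusted p = 0.209). These were the 2 called genes of 16 measured, and on the brightest probes 1 fell, and 8 adjusted over the list alone. The kinase Mvk had a log2 change of -0.75 (adjusted p = 0.0567), Mvd of -0.56 and Stard4 of -0.49. The median was -0.42 and 14 of the 16 were below 0 (camera adjusted p = 0.000569, and adjusted p = 0.499 with an estimated correlation; fry adjusted p = 0.0673). The feeder markers were higher in the same arrays, and with their median as a covariate the cholesterol median was -0.27 (adjusted p = 0.146). It was -0.18 with median scaling, against 0.18 for all probes, and -0.27 both without background correction and with the deposited normalized values.

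Mitosis genes shifted downward by camera at its preset correlation, with 13 of 15 measured members below 0 and a median of -0.28 (camera adjusted p = 0.0163, adjusted p = 0.66 with an estimated correlation, and fry adjusted p = 0.166). The medians per array overlapped slightly, with control replicate 2 at 0.055 and shChd8 replicate 3 at 0.068. The number called by limma was 0 over all genes, 4 adjusted over the list alone and 5 at an unadjusted p under 0.05. The Aurora kinases Aurka and Aurkb had log2 changes of -0.63 (adjusted p = 0.0532) and -0.58, the kinase Cdk1 -0.51 and the topoisomerase Top2a -0.48. The call was lost without shChd8 replicate 1 (median -0.17, adjusted p = 0.0692) and without shChd8 replicate 2 (0.0988). The feeder markers were higher in the same arrays, and with their median as a covariate the mitosis median was -0.06 (adjusted p = 0.543). It was -0.09 with median scaling, against 0.18 for all probes, -0.15 both without background correction and with the deposited normalized values, and -0.18 without control replicate 1.

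**Figure D3:**
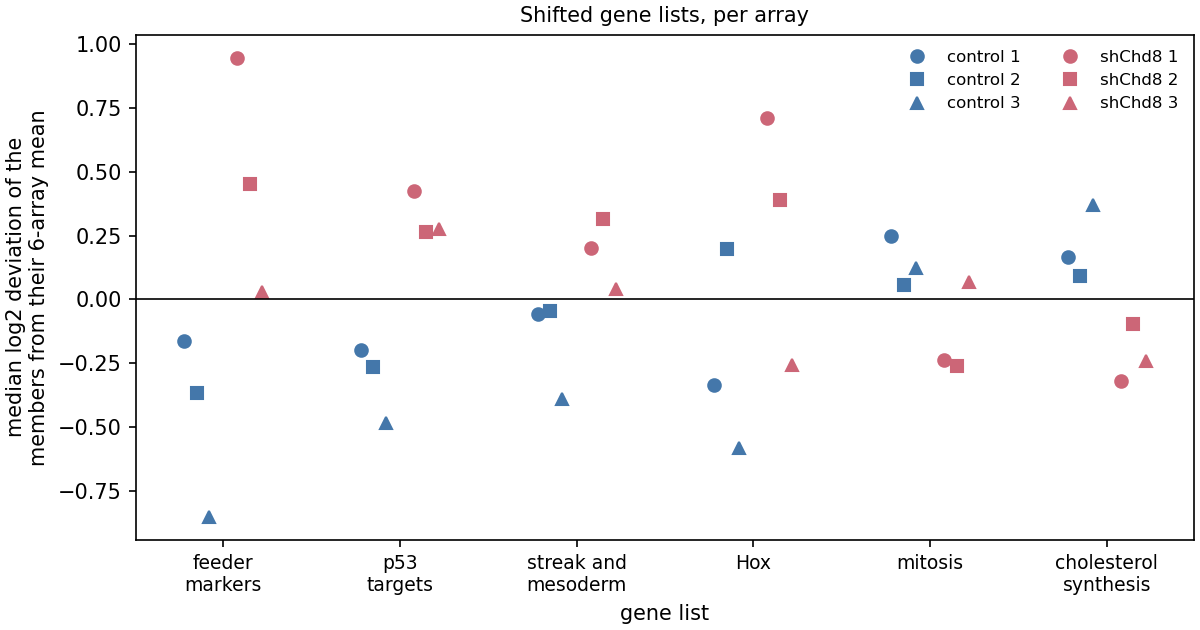
Median log2 deviation of each list's members from their mean over the 6 arrays, for the 6 lists called by camera. Colours mark the groups and symbols the replicates. For the p53 targets the shChd8 arrays lie at 0.42, 0.27 and 0.28, above all control arrays, and for the Hox and the mitosis genes the groups overlap.

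The list of pluripotency factors had 0 called by limma of 23 measured, also adjusted over the list alone, against 3 lower at an unadjusted p under 0.05, and a median of -0.11 (camera adjusted p = 0.203). Without shChd8 replicate 3 camera called it downward (median -0.23, adjusted p = 0.0232), while without shChd8 replicates 1 and 2 the median was -0.05 in each case (adjusted p = 0.679 and 0.257). With all arrays the adjusted p was 0.735 with an estimated correlation, and the median was 0.21 with the feeder covariate (adjusted p = 0.249). Its members with the lowest p were Lin28a at -0.95 (adjusted p = 0.0814), Tcl1 at -0.63, Dppa3 at -0.57 and Fgf4 at -0.49. Among Nodal and BMP targets, however, the Nodal antagonists fell: Lefty2 had a log2 change of -1.85 (SE 0.21) and Lefty1 of -1.07 (SE 0.21), whereas Pmepa1 and Id3 had 1.01 and 0.63 without a call. Of the 14 measured, 2 fell, as over the list alone, and the median was 0.35, also with Smad6, which was detected on no control array, at its bound (camera adjusted p = 0.376). Among 9 Wnt targets Sp5 rose by 1.24 (SE 0.24), 3 rose adjusted over the list alone, and Ccnd1 and Notum had 0.89 and 1.10 and Tnfrsf19 -0.21. The Wnt median was -0.02 while the mean was 0.32 and camera's direction was up (adjusted p = 0.22). The Wnt median was 0.19 and 0.09 without control replicates 1 and 3, 0.14 and 0.15 without shChd8 replicates 1 and 2, -0.19 without control replicate 2, -0.04 without shChd8 replicate 3 and 0.43 with the stricter filter.

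In each list of other lineages at most 1 gene was called, beside 502 of 9711 over all genes tested. In the endoderm list Amn fell by 1.01 (SE 0.18), the 1 call of 14 measured and also over the list alone, with Sparc at 0.71, Col4a2 at 0.69 and Dab2 at 0.54 (median 0.05, camera adjusted p = 0.639). The endoderm median was -0.0058 without control replicate 3 (camera adjusted p = 0.811). In the neural and epiblast list Sox4 rose by 0.81 (SE 0.16), 1 of 10 and also over the list alone, with Otx2 at 0.44, Dnmt3b at -0.44 and Sox11 at 0.29 (median 0.31, camera adjusted p = 0.203, and adjusted p = 0.499 with an estimated correlation). Without a filter camera called the neural list at a median of 0.20 (adjusted p = 0.0347). Of 10 trophectoderm genes 0 were called by limma, 1 rose adjusted over the list alone and 2 were higher and 2 lower at an unadjusted p under 0.05 (median 0.00080, adjusted p = 0.639), with Tfap2a at 0.72, Cdkn1c at 0.68, Tead4 at -0.55 and Krt8 at -0.49. Of 10 genes of the 2-cell stage 0 were called by limma by either count, nor at an unadjusted p under 0.05 (median 0.16, adjusted p = 0.508), and Tcstv1, Zfp352, Zscan4c and Tmem92 had 0.50, 0.45, 0.44 and -0.59. The 2-cell median was -0.05 both without control replicate 2 and without shChd8 replicate 3, and 0.56 with the feeder covariate (camera adjusted p = 0.0318, and adjusted p = 0.742 with an estimated correlation). Of 19 imprinted genes 1 fell, Phlda2, while adjusted over the list alone 7 rose and 2 fell (median 0.36, camera adjusted p = 0.114). Camera called the imprinted list with trended and robust moderation (adjusted p = 0.0495) and without shChd8 replicate 3 (median 0.49, adjusted p = 0.0282). With an estimated correlation its adjusted p was 0.499, and with the feeder covariate its median was -0.03. Zdbf2, Gnas and Cd81 had 0.60, 0.82 and 0.61.

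In the list of chromatin remodelling ATPases Chd8 and Smarca1 fell, the latter by 0.80 (SE 0.15), of 19 measured. Adjusted over the list alone, 1 rose and 2 fell. Smarca2 and Chd1l had log2 changes of 1.12 and -0.79 without a call. The median was 0.01 and the mean -0.11, with camera's direction down (adjusted p = 0.566). Linker histones had 4 measured members and were not tested as a list; 0 were called by limma over all genes, 1 fell adjusted over the list alone, and 1 was higher and 1 lower at an unadjusted p under 0.05. H1f10, H1f2, H1f5 and H1f1 had -0.74, 0.88, -0.29 and -0.08. Of 19 autism-associated genes 0 were called by limma by either count, and 3 were higher and 2 lower at an unadjusted p under 0.05 (median 0.12, adjusted p = 0.417), with Kmt2e at 0.68, Tbl1xr1 at 0.46, Setd5 at -0.47 and Med13l at -0.70.

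In each list of replication, stress and metabolism genes 1 or 2 members were called, beside 502 of 9711 over all genes tested. Whether their share differs from that over all genes was not tested. Tk1, the thymidine kinase of dividing cells, fell by 1.12 (SE 0.17), and the transcription factor E2f2 by 1.15 (SE 0.19) on 1 probe, with -0.88 on its brightest one (adjusted p = 0.0659). These were the 2 calls among 28 E2F and replication genes, and on the brightest probes 1 fell, and 4 adjusted over the list alone (median -0.17, camera adjusted p = 0.109). Camera called the list without a filter (adjusted p = 0.0332) and without shChd8 replicate 3 (median -0.26, adjusted p = 0.0152), while the median was -0.07 without shChd8 replicate 1 (adjusted p = 0.252). With all arrays the adjusted p was 0.735 with an estimated correlation, and the median was 0.07 with the feeder covariate (adjusted p = 0.783). Cdc25a and Ccna2 both had -0.64. In the list of unfolded protein and integrated stress response genes the serine synthesis enzymes Psat1 and Phgdh fell by 0.86 (SE 0.15) and 0.77 (SE 0.15), whereas Slc7a11 and Ddit3 had 1.42 (adjusted p = 0.0532) and 1.37. These 2 calls were of 25 measured, and adjusted over the list alone 1 rose and 2 fell (median 0.08, adjusted p = 0.466). With the feeder covariate the median of this list was -0.16 (camera adjusted p = 0.374). Of 20 hypoxia and glycolysis genes the prolyl hydroxylase Egln3 rose by 0.66 (SE 0.15) and the aldolase Aldoc fell by 1.11 (SE 0.23), as over the list alone, with Pfkl at -0.48 and Vegfa at 0.91. The median there was -0.10, the mean 0.0042 and camera's direction down (adjusted p = 0.95). Ifit2 rose by 0.95 (SE 0.18), 1 of 14 interferon-response genes and also over the list alone (median 0.23, adjusted p = 0.229), with Ifitm3 at 0.57, Trim25 at -0.32 and Ddx58 at 0.49.

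Of 56 cytosolic ribosomal protein genes 3 fell and 1 rose, and on the brightest probes 2 fell, as over the list alone. The 2 were Rpl22l1 with a log2 change of -1.66 (SE 0.26) and Rpl3l with -0.79 (SE 0.17), which are relatives of the standard ribosomal proteins. Rps24 had -0.68 (SE 0.15) on the called probe and 0.03 on its brightest one, and Rpl38 had 1.04 (SE 0.14) and -0.09, so their probes disagree. Rps15a and Rpl29 had -0.57 and -0.49, and the median was -0.08 (camera adjusted p = 0.123, fry adjusted p = 0.0406). Camera called the list downward with median scaling (adjusted p = 0.0351, median 0.02 against 0.18 for all probes), without a filter (adjusted p = 0.0347) and with trended and robust moderation (adjusted p = 0.0495), and not with an estimated correlation (adjusted p = 0.499). Of 65 genes of the mitochondrial respiratory chain Cox8c fell by 1.46 (SE 0.16), also over the list alone, with Cox7a1 at -0.85, Atp5a1 at -0.55 and Cox7b at -0.45. The median was 0.0030 and the mean -0.06, with camera's direction down (adjusted p = 0.639).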

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

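The fit with the feeder marker median as a covariate, and camera with an estimated correlation in it, were chosen after the data had been seen, and the other settings were planned. Chd8 was lower in all 17 alternatives, which groups without overlap favour, with limma or per-probe adjusted p from 2.62e-05 to 0.329. Its call was lost with the unmoderated test per probe (-1.39, adjusted p = 0.061) and with the covariate (-1.56, SE 0.26 against 0.15, adjusted p = 0.329). Without each array in turn its change ran from -1.47 to -1.29 and stayed called.

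The count of 502 changed genes became 1245 with normexp without controls, 1323 without background correction, 1341 with median scaling, 1326 with the deposited normalized values, 259 without a filter, 833 with the stricter filter, 1328 with trended and robust moderation, 1282 with array weights, 17 with the test per probe and 0 with the covariate. It was 27 at an adjusted p under 0.01 and 1559 under 0.1. Without each array in turn it ran from 15 to 679. With a 1.5-fold limit the counts that moved were 1339 with median scaling, 259 without a filter, 779 with the stricter filter, 1026 with trended and robust moderation, 1205 with array weights, 13 with the test per probe and 0 with the covariate (limma, with 1450 probes at an unadjusted p under 0.05 against 4292 without it), and from 15 to 679 without each array. Of the 502 genes, 464 were called the same way with normexp, 436 without background correction, 372 with median scaling, 257 without a filter and 502 with array weights. The filter changes the number of tests. Each removal of an array left the same number of samples, so that number cannot explain counts from 15 to 679. Why the count depended on the array removed was not tested, nor was the cause for the other settings.

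The 6 called lists became 0 with camera's estimated correlation (1 at an unadjusted p under 0.05), 2 with fry (the p53 targets, and the cytosolic ribosomal proteins, which were not among the 6), 2 with the covariate (the p53 targets, and the 2-cell-stage genes, which were not among the 6), 0 with the covariate and an estimated correlation (p53 targets: adjusted p = 0.366), and from 4 to 9 without each array. They became 9 without a filter (E2F, neural and ribosomal lists added) and 8 with trended and robust moderation (imprinted and ribosomal lists added). With median scaling they stayed 6, with the ribosomal list in place of the mesoderm list. The 9 without shChd8 replicate 3 added the pluripotency, E2F and imprinted lists. Against the preset correlation of 0.01, the estimated one was 0.04 for the p53 targets, 0.12 for mesoderm and 0.32 for cholesterol synthesis. It was 0.49 for mitosis, 0.53 for the feeder markers and 0.59 for the Hox genes. Of the 16 lists without a call 6 were called in at least 1 setting, and the median of 11 changed sign in at least 1 other than median scaling, which moved all probes. Of 20 alternatives the p53 call was kept in 18, the feeder, Hox and cholesterol calls in 16 each, the mitosis call in 14 and the mesoderm call in 7. Median scaling moved the median of all probes from -0.01 to 0.18 and left the direction of the 6 lists as it was. With the covariate the feeder list, from which the covariate was made, changed to -0.14 and the Hox list to -0.24. Genes without a call that changed sign with it were Fgf4 (0.21), H1f5 (0.45), H1f1 (0.81), Col4a2 (-0.15), Dab2 (-0.055), Pmepa1 (-0.0064), Hoxa5 (-0.53), Hoxd8 (-0.18) and Hoxd9 (-0.00065). Tnfrsf19 was 0.0089 and H1f1 0.052 with median scaling, and H1f1 was 0.046 with array weights. Without each array Tnfrsf19 ran from -0.39 to 0.049 and H1f1 from -0.38 to 0.19. The cause was not tested.

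No paired analysis was possible because the labels give the groups no shared replicate numbers. A block for the slide was not run, since all arrays lay on 1 slide. With the stricter filter 17 of the 110 other named genes gave no value, and 2 gave none without an shChd8 array. Probes near background limit what can be read, since 36.4% to 38.5% of probes were detected per array.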

Other observations

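The tests of the feeder markers and the fits with their median as a covariate were chosen after the data had been seen, as were the germline and serine lists. Among the genes that fell, 19 known from the germline were noticed after the calls had been seen, and whether the calls hold more of them than chance would give was not tested. They included Rhox5, a homeobox gene of the reproductive tract, at -1.66 (SE 0.14), Stra8, a gene of meiotic entry, at -1.12 (SE 0.15), and the Tudor domain genes Tdrd12 and Tdrkh of the piRNA pathway at -1.29 (SE 0.22) and -1.26 (SE 0.20). A list of other germline and meiosis genes, written before their values were looked at but with called genes left out, had 32 measured members, of which 24 were below 0. Their median was -0.28 (camera p = 0.0279, and p = 0.362 with an estimated correlation). That limma called 0 was fixed by leaving out called genes, and 12 had an unadjusted p under 0.05 in either direction. Of these, Taf7l had a log2 change of -1.08 (limma adjusted p = 0.051), whereas Tdrd7 had 0.81 (0.0532) and Taf9b 0.63 (0.0989). Whether germline genes as a whole were lower therefore stays open.

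A smaller group of called genes belongs to serine, glycine and one-carbon metabolism. It too was noticed after the calls had been seen, and whether the calls hold more such genes than chance would give was not tested. Beside Psat1 and Phgdh, the glycine decarboxylase Gldc had a log2 change of -1.37 (SE 0.15), Gcat -1.07 (SE 0.17), Mthfd2 -1.04 (SE 0.21) and Shmt1 -0.96 (SE 0.15). Of the other members 14 were measured, and 10 of these lay below 0, with a median of -0.24. Their shift was not past the threshold (limma's camera, unadjusted p = 0.154). This leaves open whether the pathway as a whole may have been lower, because called genes had been left out of that set.

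With camera at the preset correlation the feeder markers had the lowest p of the lists, while the p53 targets had it with an estimated correlation (adjusted p = 0.259 against 0.499) and with fry (0.00953 against 0.166). The levels of the brightest markers were 12.28 in control and 12.98 in shChd8 for Ccn2, 11.56 and 12.73 for Acta2, 10.99 and 12.36 for Lgals1 and 10.70 and 12.11 for Timp2, whereas Thy1 was 9.65 and 9.63; how many of the markers ES cells also express was not tested, and 1, Dcn, is on the imprinted list too. If feeder cells took a larger share of the shChd8 cultures, the markers should also move together between arrays of 1 group. Their within-group deviations correlated with the median of the other markers at a median of 0.859. For 1000 random lists of like brightness the median was 0.035, and 100% of these lay below. A varying share of feeder cells would give this, but so would markers regulated together within 1 cell type. A comparison with random genes cannot tell these apart. A response of the ES cells to Chd8 knockdown cannot be told apart from a larger share of feeder cells, since either would raise the markers in the shChd8 arrays. The lowest shChd8 array lay above the highest control array by 0.19, less than the SD of 0.35 among the control arrays. A gap of another size would not have separated them either.

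A larger share of feeder cells may also lie behind the rise of the Hox list. With the feeder marker median as a covariate -48.8% of its median change was left, and between -108.1% and 30.3% when any 1 array was left out, so the change was not kept. The median went from 0.50 to -0.24 and camera's adjusted p from 0.00303 to 0.465. A loss of the rise is what Hox transcripts of feeder fibroblasts would give. However, the covariate overlaps with the groups, with 66.1% of its variance between them, so this fit cannot tell that apart from a response in the ES cells. Such a response stays open and untested.

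For the p53 targets the covariate left 32.9% of the median change, 0.26 of 0.79, and up to 51.5% when an array was left out, while camera called the list at the preset correlation (adjusted p = 0.000303) and not with an estimated one (adjusted p = 0.366, and 0.259 without the covariate). Those values lie on both sides of the limit of 50% that was set. A share of feeder cells cannot be told apart from a change in the ES cells here, and values on 1 side of the limit would not have separated them either. The reason is that the covariate itself followed the groups, with 66.1% of its variance between them. With it all 502 called genes kept their sign, and the median change went from 0.96 to 0.74 for those that rose and from -0.95 to -0.84 for those that fell. Their median standard error went from 0.17 to 0.28, and limma called 0, with 1450 probes at an unadjusted p under 0.05. The covariate overlaps with the groups, which raised the standard error per unit of residual SD from 0.816 to 1.40 for every probe. How much of the loss came from this and how much from the smaller changes was not separated.

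Other splits of the 6 arrays into 3 and 3 were counted. The real split called 502 genes, also with the 1.5-fold limit, and the highest of the other 9 called 0 with limma, with 310 to 1849 probes at an unadjusted p under 0.05 against 4292, so that 1 of the 10 splits gave as many. For the lists 4 of the 10 splits, the real one included, gave as many as the real 6, and others gave 7, 8 and 10. The number of called lists therefore did not set the real split apart. For the genes the number of splits is a limit, since with 10 splits no share under 0.05 can be reached. Each of the other 9 splits also had arrays of both groups on both sides. Any difference between the groups, also one from array position, then adds to the spread within a side and lowers the calls. The count of 0 is therefore no measure of what chance gives. The split of control replicates 1 and 3 and shChd8 replicate 3 against the rest gave the 10 lists.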
